A study of Mus musculus with 54 samples.

How the data were processed

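RNA-seq counts of 40 libraries from mouse cXEN cells were analysed, 2 per group in 20 groups. The series also holds 14 chromatin samples (ATAC-seq and CUT&RUN), which were not analysed here. Per the labels, the authors made libraries from total RNA, aligned reads with HISAT2 to mm10 and counted reads per gene with HTSeq; Trimmomatic and Bowtie2 are also listed, and no version, annotation release or strand setting is stated. The deposited values are raw counts, whole numbers for 47729 Ensembl genes per library, followed by totals for reads outside genes, ambiguous, unaligned and not uniquely aligned reads. Those totals were kept apart from the genes. Gene names came from an Ensembl to symbol table, which named 47224 of the genes and left 505 without a symbol; 120 genes shared a symbol with another and were kept apart by ID. Coordinates came from a RefSeq table on mm10.

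Libraries held 16.2 to 42.5 M gene reads. Reads in no annotated gene made up 3.40 to 8.39% of all reads, mitochondrially encoded transcripts 0.49 to 1.69% of gene reads, and the 10 most abundant genes 5.88 to 10.5%. Within groups, the spread of counts between both libraries over that of counting alone (chi-square per degree of freedom) ran from 1.48 to 57.4, highest for BMP4 at 24 h, Sox17 degradation at 24 h (38.9), the parental cells (16.4), Gata6 degradation at 48 h in the FoxA2 mutant (15.1) and the Gata6-FKBP 0 h control (13.7). Nothing in the labels says that replicates come from separate cultures, so p-values measure only the spread between these samples. Replicate numbers did not pair libraries across groups: over 18 comparisons the correlation of replicate differences ran from −0.69 to 0.57, above 0.1 in 5 and below −0.1 in 8, so replicates were treated as unpaired and a block for replicate number was run as an alternative.

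A quasi-likelihood model of edgeR 4.0.16 in R 4.3.3 was fitted once over all 40 libraries, with a mean per group, TMM scaling and edgeR's default filter on low counts, which left 14625 genes. It had 20 residual degrees of freedom, a common dispersion of 0.0068 and a biological coefficient of variation of 8.2%. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called changed. Standard errors of log2 changes were taken as the change divided by the square root of its F statistic. Tests of a difference of responses used the contrast of both changes. A change against a group without any read is given as a lower bound, with 3 counts over that group's libraries as the floor, and floors cover counting error only.

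Gene lists were compared with all other genes by camera of limma 3.58.1 with the preset correlation of 0.01, again with a correlation estimated from the data, and by fry, with adjustment over the 504 tests of 24 lists in 21 comparisons. The lists, of 8 to 24 measured genes, covered primitive endoderm and XEN identity, parietal, visceral and anterior visceral endoderm, definitive endoderm and gut, pluripotency and epiblast, trophoblast, mesoderm, neural, endothelial, fibroblast (feeder cell), epithelial and mesenchymal genes, basement membrane, responses to BMP and SMAD1/5, WNT, FGF and ERK, p53 and interferon, the cell cycle, ER stress, cholesterol synthesis, glycolysis and hypoxia, and mitochondrially encoded transcripts.

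The groups, comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. That rule names Gata6, Sox17, Foxa2 and Gata4; in each comparison, the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM, no overlap between the groups and a full gene symbol; for each list, the 2 members with the smallest adjusted p in the direction most called members took; and in each test of a difference, the 4 most positive and 4 most negative genes. A few genes this rule names are not reported here. Genes named for 1 comparison are also given in others where their levels are needed.

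Alternatives were median-of-ratios scaling, no filter on low counts, DESeq2 1.42.0, a fit to only the libraries compared, the replicate block, and leaving out each library in turn, where the lone sample of a group is assumed to vary like the others. Chosen after the data were seen were the log2 of reads outside genes per 100 gene reads as a covariate, the steps between successive times and the FoxA2 mutants against parental cells. Also chosen then was a comparison of the BMP4 series at 0 h with the other untreated groups on mean log2 of CPM plus 0.5, over genes at least 3 log2 units apart between groups, each gene counted for the group nearer in level. The covariate's slope passed the threshold for 5813 genes, 2630 positive and 3183 negative. The procedure was tested on counts drawn from each gene's mean level over all libraries, the library sizes and the fitted dispersions, alike for every group. The wider spread of some pairs, such as BMP4 at 24 h, was therefore not imitated. With known changes put into the 48 h libraries of Gata6 degradation, the procedure recovered 47.6% of changes of 1.5-fold, 64.5% of 2-fold and 84.1% of 4-fold. A further set of genes was given a small common shift. Of the procedure's 138 calls there, 5.8% fell on genes where nothing was put in. In the 48 h Sox17 comparison of the same drawn counts, also without any change put in, edgeR called 0 genes.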

Results

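The series examined cXEN cells, a mouse stem cell line of the extraembryonic endoderm, the tissue that forms the yolk sac and surrounds the early embryo. RNA was profiled by RNA-seq in 40 libraries, in 20 groups of 2. In a pair of lines the transcription factor Gata6 or Sox17 carried an FKBP tag, through which the small molecule dTAGV1 marks the protein for degradation. Each line was sampled at 0, 6, 24, 48, 72 and 96 h of 500 nM dTAGV1, and the labels give the 0 h cells vehicle. The same lines with a FoxA2 mutation were sampled at 0 and 48 h. Parental cXEN cells made up another group. A further series received 25 ng/ml BMP4, a ligand that turns such cells toward visceral endoderm, in serum-free medium for 24 or 72 h, and its 0 h cells had 1% serum and no BMP4. Its sample titles name XEN cells and its genotype label the Gata6-FKBP line. At 0 h it lay nearer that line than the parental cells in 276 of 277 genes, and nearer than the Sox17-FKBP line in 128 of 133, among genes at least 3 log2 units apart between those lines. Reads assigned to genes numbered 16.2 to 42.5 M per library, with a median of 21.7 M. Levels below are counts scaled to library size (CPM) as mean ± SD of 2 libraries, and log2 changes carry ± their standard error. For each gene called below, both libraries of 1 group lay above both of the other, an arrangement chance gives in 1 of 3 genes.

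The first question was what happened to the RNA of the targets themselves, since neither protein was measured here. Gata6 (ENSMUSG00000005836; mm10 chromosome 18, 11052510 to 11085636) encodes a zinc-finger factor of primitive endoderm. In its own line its RNA stood at 269 ± 3.32 CPM at 0 h and 282 ± 5.48 at 6 h, which did not pass the test (log2 change 0.07 ± 0.06, adjusted p = 0.49). By 96 h it had risen to 328 ± 0.54 (0.29 ± 0.06, adjusted p = 0.00044), a call lost with the reads outside genes as a covariate (adjusted p = 0.08). Sox17 (ENSMUSG00000025902; chromosome 1, 4490928 to 4497426), an HMG-box factor of endoderm, went in its own line from 265 ± 12.4 CPM at 0 h to 294 ± 7.29 at 6 h (0.15 ± 0.07, adjusted p = 0.5). Its RNA then fell to 169 ± 3.57 at 96 h (−0.65 ± 0.07, adjusted p = 5.5e-08). In the Sox17-FKBP line Gata6 RNA rose under dTAGV1, from 341 ± 5.68 to 469 ± 18.9 CPM at 48 h (0.46 ± 0.06, adjusted p = 9.1e-07). Foxa2 (ENSMUSG00000037025; chromosome 2, 148042877 to 148046969) and Gata4 (ENSMUSG00000021944; chromosome 14, 63198914 to 63271712) encode further endoderm factors. After 48 h of Gata6 degradation, Foxa2 fell from 124 ± 9.66 to 101 ± 3.76 CPM (adjusted p = 0.0015) and Gata4 from 828 ± 61.7 to 720 ± 38.7 (adjusted p = 0.019). Neither passed with the covariate (adjusted p = 0.41 and 0.46) or without the Gata6 line's 0 h replicate 2 (0.061 and 0.27), and Gata4 also missed the threshold under median-of-ratios scaling (0.051), with only these libraries (0.09) and without the 48 h replicate 2 (0.2).

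The early times of Gata6 degradation asked which genes respond first. Socs3, an inhibitor of cytokine signalling, rose from 124 ± 9.21 CPM to 247 ± 9.84 at 6 h (log2 change 0.99 ± 0.13, adjusted p = 0.00018) and stood at 273 ± 9.53 at 24 h. The kinase gene Nuak1 went from 13.7 ± 1.78 to 25.6 ± 1.33 and then 34.1 ± 0.55 CPM. At 24 h Abcg1, a sterol exporter, rose by 1.38 ± 0.20 and Rasd1, a Ras-like GTPase gene, by 1.25 ± 0.14. Larger falls were read for Mphosph8, of the HUSH silencing complex, at 6 h (−1.36 ± 0.27, adjusted p = 0.0029) and for Hmgn5, which binds nucleosomes, at 24 h (−1.55 ± 0.27, adjusted p = 0.00046). Of 16 measured genes of the FGF and ERK response, 6 rose and none fell at 24 h (7 adjusted over the list alone), among them Etv5 (0.67 ± 0.09) and the ERK phosphatase gene Dusp4 (0.59 ± 0.11). That list was higher by camera (adjusted p = 0.00064) and with an estimated correlation (0.038). In all, 2027 of 14625 tested genes changed at 6 h, 502 up and 1525 down, and 3131 at 24 h, 1040 up and 2091 down. Most changes were small: by at least 1 log2 unit, 20 rose and 223 fell at 6 h, and 60 rose and 422 fell at 24 h. These counts rested on the 0 h control: without its replicate 1, 9 genes passed at 6 h and 292 at 24 h, and Mphosph8 (adjusted p = 0.28) and Hmgn5 (0.068) were no longer called. Leaving out the 6 h group's replicate 1 gave 78 genes (Mphosph8, adjusted p = 0.098) and its replicate 2 gave 822, while leaving out the 24 h group's replicate 1 or 2 gave 1282 or 1471. With only the libraries compared 1265 genes passed at 6 h, and with the covariate 1087. Mitochondrially encoded transcripts, a sign of RNA quality, were down as a list at 6 h, with 2 of 12 past the test (2 adjusted over the list alone). That call (0.046) was lost at adjusted p = 0.44 with an estimated correlation, at 0.16 with the covariate, and without replicate 1 of 0 h (0.35) or of 6 h (0.1).

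Between 24 and 48 h of Gata6 degradation, genes that had been nearly silent reached high levels. Vgf, which encodes a secreted neuropeptide precursor, rose from 3.13 ± 0.03 CPM at 0 h to 80.5 ± 2.92 at 48 h (4.68 ± 0.19, adjusted p = 3.4e-16). The peptide hormone gene Adm (4.34 ± 0.25), the Notch ligand gene Dll1 (4.21 ± 0.37) and the immediate early gene Egr1 (3.53 ± 0.22) rose as well. Among the largest falls were the WNT ligand gene Wnt7b, from 21.2 ± 4.29 to 3.04 ± 0.94 CPM (−2.80 ± 0.21, adjusted p = 4.1e-11), the mitochondrial gene Chchd10 (−2.60 ± 0.22), and the enzyme genes Acot7 (−2.40 ± 0.18) and Vnn1 (−2.33 ± 0.13). In all, 5864 genes changed at 48 h against 0 h, 2656 up and 3208 down, but 2963 up and 2905 down under median-of-ratios scaling. Large changes were mostly rises: among the 5864, 870 rose and 428 fell by at least 1 log2 unit. Reads outside annotated genes moved with this course, at 7.56 to 8.01 per 100 gene reads from 48 h on against 5.88 at 0 h. With that measure as a covariate, 60.6% of the 48 h calls kept their direction and call.

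**Figure D1:**
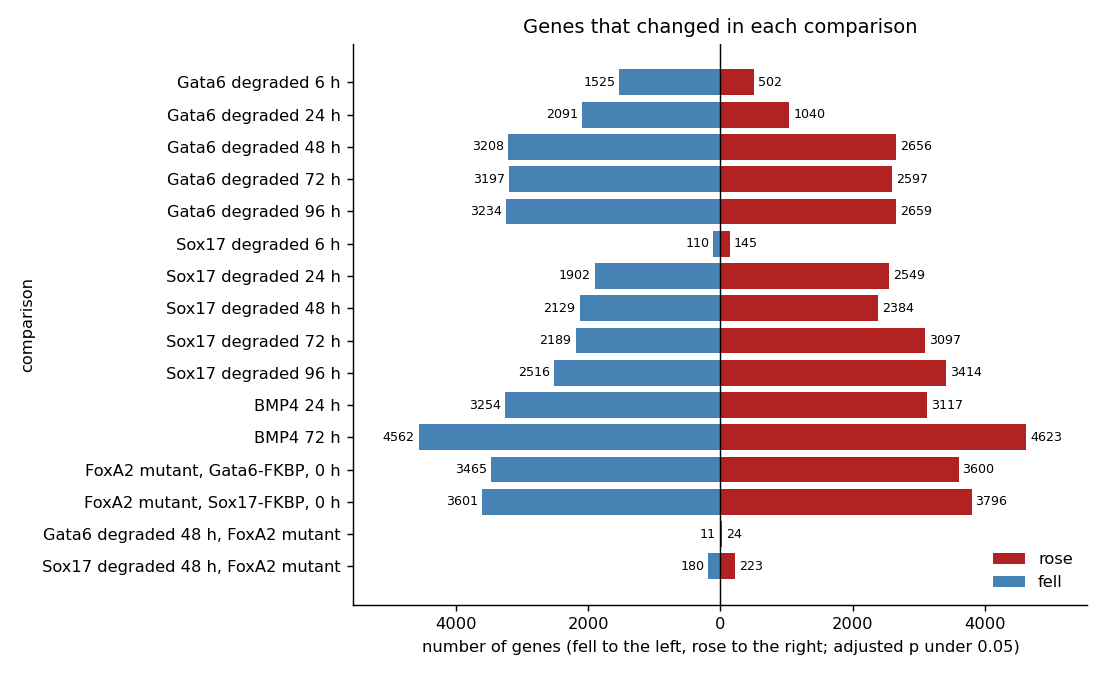
Number of genes that rose (right) and fell (left) at an adjusted p under 0.05 in each comparison with its 0 h or FoxA2-intact group, from 40 libraries. The bars for 48 h of degradation in the FoxA2 mutants hold 35 and 403 genes, against 5864 and 4513 in the intact lines.

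Several gene groups moved together in the Gata6 course. Endothelial genes were higher at 48 h, with 10 of 11 up (10 adjusted over the list alone), including the VEGF receptor gene Flt1 (59.7 ± 2.81 to 143 ± 1.87 CPM, 1.26 ± 0.12) and the cadherin gene Cdh5 (0.92 ± 0.07). That call (camera adjusted p = 2.1e-08) held with an estimated correlation (0.00065). FGF and ERK response genes were higher too, with 10 of 16 up and none down (11 up and 1 down adjusted over the list alone), such as Dusp6 (2.77 ± 0.17) and Ier3 (2.41 ± 0.13); the camera p of 5.7e-08 held as well (0.003). Cell cycle genes were lower, with 18 of 24 down (18 adjusted over the list alone), among them Ccna2 (−0.95 ± 0.05) and Rrm2 (−0.91 ± 0.05), at a camera p of 8e-12 and 0.009 with an estimated correlation. Epithelial genes fell in 12 of 20 cases and rose in 1, including the splicing regulator gene Esrp2 (−1.75 ± 0.10) and the protease gene St14 (−1.62 ± 0.13), with 5.3e-05 by camera and 0.029 with an estimated correlation. Glycolysis and hypoxia genes rose in 14 of 20 cases, led by Egln3 (2.16 ± 0.15) and Bnip3 (1.89 ± 0.14), a camera call (8.1e-08) lost at adjusted p = 0.14 with an estimated correlation. Cholesterol synthesis genes fell in 14 of 22 cases and rose in 3, for example Sqle (−0.83 ± 0.08), and that call (0.0034) was also lost (adjusted p = 0.074 with an estimated correlation). Of 14 interferon response genes, 7 rose at 48 h, among them Xaf1 (1.22 ± 0.12), with a call of 0.019 lost at adjusted p = 0.07 with an estimated correlation.

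Later times were compared with 0 h in the same way. Vgf stood at 84.1 ± 1.60 CPM at 72 h and 67.3 ± 0.79 at 96 h. Acvrl1, a BMP9 receptor gene of endothelium, rose from 0.28 ± 0.06 CPM at 0 h to 10.1 ± 1.23 at 72 h and 9.92 ± 2.70 at 96 h (5.14 ± 0.42, adjusted p = 3.9e-10). Pecam1, an endothelial adhesion gene, reached 9.62 ± 1.94 CPM at 96 h (3.64 ± 0.29, adjusted p = 9.5e-11), and Mpzl2 fell by 2.45 ± 0.13. The interferon list, with 7 of 14 genes up at 72 h, was higher at adjusted p = 0.006 and held with an estimated correlation (0.037). At 96 h, again with 7 up, its call of 0.012 was lost at adjusted p = 0.054 with an estimated correlation. Changed genes numbered 5794 at 72 h, 2597 up and 3197 down, and 5893 at 96 h, 2659 up and 3234 down. By at least 1 log2 unit, 825 rose and 464 fell at 72 h, and 865 rose and 384 fell at 96 h. Which direction held more genes at 72 h turned with the scaling: median-of-ratios scaling gave 3071 up and 2733 down, and DESeq2 2979 up and 2713 down. At 96 h median-of-ratios scaling gave 2932 up and 2928 down. With the covariate, 71.1% and 53.6% of these were kept.

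Steps between successive times, chosen after the data were seen, placed most of the change in 1 interval. From 6 to 24 h, 4 genes passed: Hdc, the histamine-forming enzyme, rose by 0.89 ± 0.16, Gpc4, a cell surface proteoglycan, by 0.70 ± 0.10, and the chaperone gene Clu by 0.53 ± 0.09, while Enpep, an aminopeptidase gene, fell by 0.84 ± 0.11. Without replicate 1 or 2 of 6 h, 0 or 1 gene passed, and without replicate 1 or 2 of 24 h, 2 or 0, while no filter gave 14, DESeq2 11 and the covariate 17. From 24 to 48 h, 7912 genes changed: Adm rose by 3.93 ± 0.23 and the lipoprotein receptor gene Vldlr by 3.30 ± 0.16, while Socs3 turned from 273 ± 9.53 CPM to 49.0 ± 3.21 (−2.48 ± 0.14, adjusted p = 1.4e-13) and Gadd45g fell by 2.39 ± 0.15. With the covariate this count was 3336, and 2729 of the step's genes kept their call. Between 48 and 72 h edgeR called 0 genes (884 at an unadjusted p under 0.05; DESeq2 2), and between 72 and 96 h again 0 (1222 unadjusted; DESeq2 49), against 118 and 324 with no filter on low counts. Without the 72 h group's replicate 2 these counts were 2 and 1, and without the 96 h group's replicate 2 the later step gave 4.

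**Figure D2:**
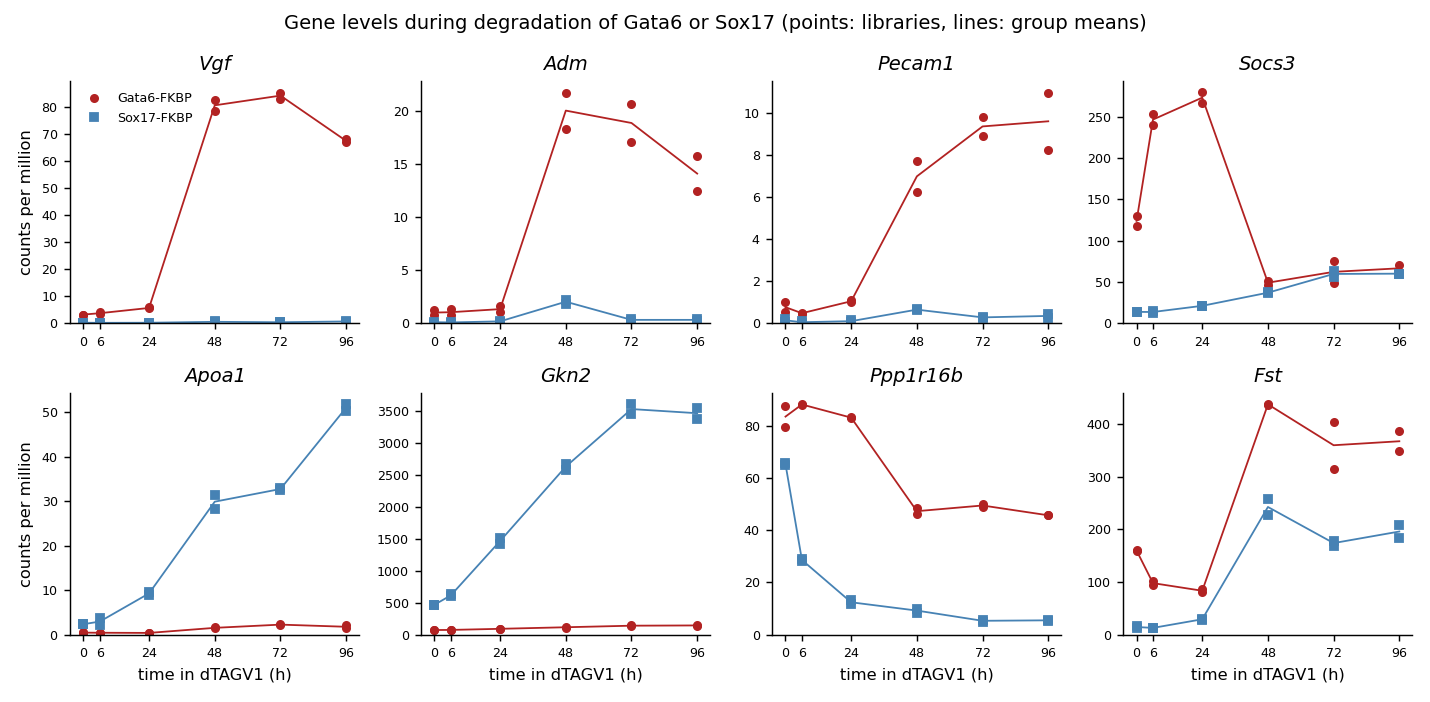
Levels of 8 genes in CPM against hours in dTAGV1, in the Gata6-FKBP and Sox17-FKBP lines, with a point per library and a line through group means. Vgf in the Gata6-FKBP line went from 5.59 at 24 h to 80.5 at 48 h, while Gkn2 in the Sox17-FKBP line climbed from 469 at 0 h to 3472 at 96 h.

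Sox17 degradation was read from 6 h on in the same way. Ppp1r16b, a phosphatase regulator known from endothelium, fell from 65.2 ± 0.40 to 28.6 ± 0.51 CPM (−1.19 ± 0.09, adjusted p = 1e-08), and it continued to 12.4 ± 1.04 at 24 h and 5.50 ± 0.21 at 96 h. The sterol regulator gene Insig1 fell by 0.92 ± 0.10 (adjusted p = 2e-06), Myc by 0.88 ± 0.09, the glutamate transporter gene Slc1a3 by 0.94 ± 0.13, and Sall4, a zinc-finger factor of stem cells and primitive endoderm, by 0.79 ± 0.07. Rises included Nudt11 (0.77 ± 0.10), the receptor gene Notch1 (0.74 ± 0.11) and Marveld2, a tight junction gene (0.70 ± 0.11). Cholesterol synthesis genes were lower as a list, with 4 of 22 down (8 adjusted over the list alone), Insig1 and Cyp51 among them, at a camera p of 7.4e-13 and 0.00043 with an estimated correlation. Epithelial genes were higher (4 of 20 up, 6 adjusted over the list alone; 4.6e-07, and 0.009 with an estimated correlation), and primitive endoderm genes lower (2 of 18 down, 2 adjusted over the list alone; 0.00032 and 0.045). Changed genes numbered 255, 145 up and 110 down, but falls were more numerous with no filter (143 up, 253 down), with only these libraries (562 and 725) and without replicate 1 of 0 h (31 and 42). Leaving out the 0 h replicate 1 or 2 gave 73 or 86 and leaving out the 6 h replicate 1 or 2 gave 83 or 87, while DESeq2 called 383, no filter 396, the covariate 456 and a fit of only these libraries 1287.

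At 24 h of Sox17 degradation, epithelial genes had moved up. Of 20 such genes 14 rose and 1 fell (14 and 1 adjusted over the list alone), including E-cadherin Cdh1 (11.2 to 28.6 CPM, 1.36 ± 0.10) and the keratin gene Krt18 (565 to 1290 CPM, 1.19 ± 0.10), a camera call of 1.5e-08 that held with an estimated correlation (0.0042). Visceral endoderm genes rose in 8 of 22 cases and fell in 4 (9 and 4 adjusted over the list alone), a call of 0.0043 lost at adjusted p = 0.12 with an estimated correlation and at 0.096 with the covariate. Sall3 rose by 2.01 ± 0.21, the apolipoprotein gene Apoa1 by 1.97 ± 0.15 and the keratin gene Krt20 by 1.86 ± 0.20. Sall4 fell further (−1.23 ± 0.07), and 15 of 22 cholesterol synthesis genes were down (15 adjusted over the list alone; 5.2e-06 by camera, 0.01 with an estimated correlation). Mitochondrially encoded transcripts were down in 7 of 12 cases, a call of 0.0042 lost at adjusted p = 0.24 with an estimated correlation. Changed genes numbered 4451, 2549 up and 1902 down, against 2035 up and 2234 down with no filter. By at least 1 log2 unit, 314 of the 4451 rose and 355 fell. The 24 h replicates stood further apart than most pairs: without replicate 1 of 24 h the count was 2007, without replicate 1 of 0 h 2595, and with only these libraries 625.

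At 48 h of Sox17 degradation genes of visceral endoderm, the layer that takes up and carries nutrients, were higher as a list. Apoa1 rose from 2.36 ± 0.01 CPM at 0 h to 29.9 ± 2.26 at 48 h (3.66 ± 0.14, adjusted p = 7.9e-17), and the thyroxine carrier gene Ttr from 32.7 ± 1.86 to 105 ± 0.45 (1.69 ± 0.11). The oxygen sensor gene Egln3 (4.75 ± 0.18), Vldlr (4.30 ± 0.17), the activin antagonist gene Fst (4.06 ± 0.11) and Igfbp5 (3.60 ± 0.19) rose as well. Falls were read for Mfsd2a, a transporter of lysolipids (−3.07 ± 0.22), the drug exporter gene Abcb1a (−2.85 ± 0.29), the myosin gene Myh7 (−2.63 ± 0.12) and Flt1 (−2.55 ± 0.16). Of 22 visceral endoderm genes 13 rose and 3 fell (13 and 3 adjusted over the list alone; camera 8.1e-08, 0.009 with an estimated correlation), and of 20 parietal endoderm genes 11 rose and 3 fell (11 and 3; 1.2e-05 and 0.037), including the matrix gene Nid1 (1701 to 4479 CPM). Basement membrane genes rose in 16 of 23 cases, a call of 1.9e-06 lost at adjusted p = 0.087 with an estimated correlation. Cholesterol synthesis genes fell in 17 of 22 cases and rose in 1, with Cyp51 down by 1.01 ± 0.07 (1.6e-10, and 0.00097 with an estimated correlation). The p53 list was lower, with 8 of 17 down (9 adjusted over the list alone), including Gtse1, which itself acts in the cell cycle (0.0084, and 0.041). ER stress genes rose in 16 of 18 cases and fell in 1 (0.00013; lost at adjusted p = 0.093 with an estimated correlation). Changed genes numbered 4513, 2384 up and 2129 down, and a fit of only these libraries gave 6895, 3429 up and 3466 down.

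By 96 h of Sox17 degradation the mucin gene Muc5b had risen from 0.31 ± 0.10 to 13.8 ± 1.92 CPM (5.49 ± 0.38, adjusted p = 6e-11) and the retinol carrier gene Rbp4 from 6.76 to 83.7 CPM (3.64 ± 0.10). Fibronectin Fn1 rose from 16.2 ± 1.37 to 288 ± 43.1 CPM (4.15 ± 0.16, adjusted p = 2.3e-17), the integrin gene Itgb3 by 3.64 ± 0.19 and Sytl2 by 4.56 ± 0.23. The gastrokine genes Gkn1 and Gkn2, secreted proteins known from stomach lining, rose by 3.26 ± 0.12 and 2.89 ± 0.11, Gkn2 reaching 3472 ± 120.0 CPM. Dpp4, a cell surface peptidase gene, fell by 2.69 ± 0.20, and the WNT inhibitor gene Dkk1 had fallen by 2.37 ± 0.13 at 72 h. Mesenchymal genes were higher at 96 h, with 10 of 20 up (12 adjusted over the list alone; camera 8e-06, 0.011 with an estimated correlation), alongside epithelial genes (12 up and 1 down of 20; 4.1e-06 and 0.014), with Cdh1 at 59.4 CPM and Krt19 up by 1.92 ± 0.12. Cell cycle genes were lower in 21 of 24 cases (22 adjusted over the list alone; 3.9e-14 and 0.0043), Ccne1 by −1.27 ± 0.09 and Ccna2 by −0.68 ± 0.05. Changed genes numbered 5286 at 72 h, 3097 up and 2189 down, and 5930 at 96 h, 3414 up and 2516 down. With only the libraries compared the excess of rises was gone, at 3854 up and 3916 down for 72 h and 3939 up and 4048 down for 96 h.

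Between successive Sox17 times the counts were 1902 from 6 to 24 h, 4852 from 24 to 48 h, 1008 from 48 to 72 h and 432 from 72 to 96 h. In the 24 to 48 h step Egln3 rose by 4.27 ± 0.18 and Egr1 by 4.23 ± 0.30, while the contractile genes Myh11 (−2.96 ± 0.23), Tagln (−2.74 ± 0.12) and Actg2 (−2.58 ± 0.18) fell. Tgm2, a transglutaminase that joins matrix proteins, rose in the last steps, from 12.9 ± 0.96 CPM at 48 h to 64.7 ± 2.33 at 72 h and 322 ± 32.4 at 96 h. With the covariate the 24 to 48 h count was 2549, with only these libraries 1126, without the 24 h replicate 1 2268 and without the 48 h replicate 2 2947. The 6 to 24 h step gave 594 without the 24 h replicate 1, 3733 without its replicate 2, and 897 or 698 without replicate 1 or 2 of 6 h. With only the libraries compared edgeR called 0 genes in that step (1820 at an unadjusted p under 0.05). DESeq2 was run only over all libraries, where it called 2216 against 1902 by edgeR. Leaving out any 1 of the 4 libraries gave 521 to 580 for the 48 to 72 h step and 130 to 240 for the 72 to 96 h step. With only the libraries compared these later steps gave 3446 and 2812, and with the covariate the last gave 716.

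Whether both degradations reach the same genes was read from the overlap at 48 h. Both raised 1097 genes and both lowered 1427, where independent responses would share 433 and 467, and 284 genes went opposite ways. Across genes, which are not independent replicates, the changes correlated at Pearson r = 0.26 and Spearman rho = 0.40. Both lines received the same compound over the same times, and no untagged cells received it. Effects of the compound or of culture shared by both lines were therefore not separated from those of degradation. A direct test found 2503 genes whose responses differed, 901 more positive under Gata6 loss and 1602 under Sox17 loss. That lean shrank to 1225 and 1276 with no filter and to 1098 and 1412 with the covariate. At differences of at least 1 log2 unit it was 327 and 346. Each factor was degraded in 1 line only, and the lines differed before treatment. The factor lost was therefore not separated from the line in this test or in the lists below. Ankrd1, a cardiac and YAP-responsive gene (4.17 ± 0.42), Flt1 (3.81 ± 0.20) and the membrane protein gene Emp1 (3.45 ± 0.43) lay on the Gata6 side. On the Sox17 side were Trmt9b (−3.93 ± 0.43), carbonic anhydrase Car2 (−3.87 ± 0.19), the netrin receptor gene Unc5b (−3.24 ± 0.36) and the ephrin gene Efna5 (−3.17 ± 0.45). FGF and ERK genes leaned to Gata6 loss in 11 of 16 cases (11 adjusted over the list alone; camera 1.3e-16, 0.00019 with an estimated correlation). Epithelial genes leaned to Sox17 loss in 12 of 20 cases against 1 (3.1e-07 and 0.009), as did visceral endoderm genes in 10 of 22 against 1 (1.7e-05 and 0.028). Endothelial genes leaned to Gata6 loss as a list, with 2 of 11 past the test and 1 opposite (0.001 and 0.017).

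**Figure D3:**
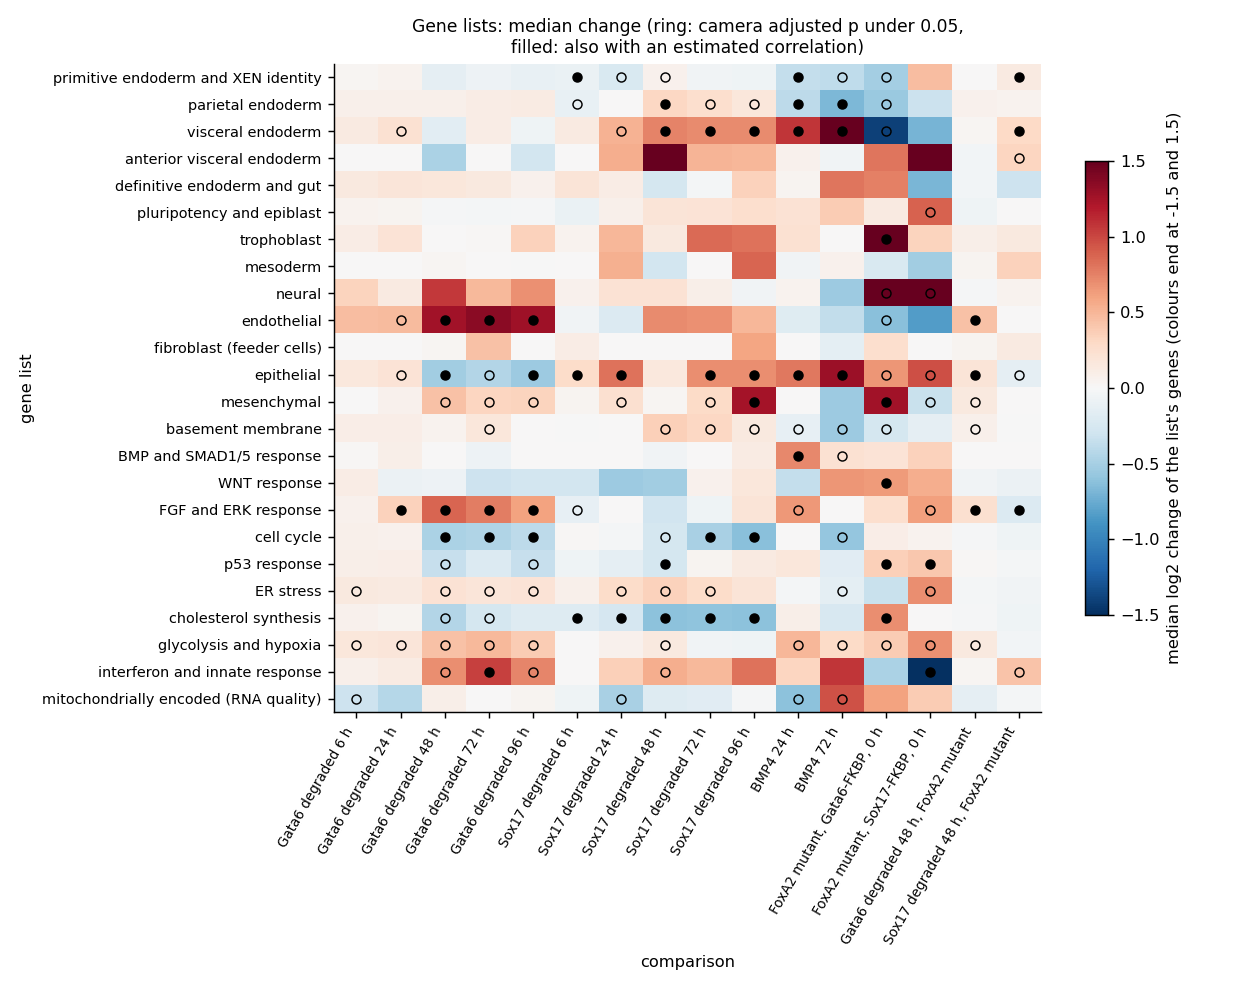
Median log2 change of 24 gene lists (vertical) in 16 comparisons (horizontal), with colours ending at −1.5 and 1.5, a ring for a camera adjusted p under 0.05 and a filled ring where the call also held with an estimated correlation. Endothelial genes carried filled rings at 48, 72 and 96 h of Gata6 degradation, and visceral endoderm genes at 48, 72 and 96 h of Sox17 degradation.

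Known targets and inhibitors of BMP signalling rose within 24 h of BMP4. Id3 rose from 0.47 ± 0.09 to 182 ± 41.7 CPM (8.58 ± 0.26, adjusted p = 3.8e-19), Id1 from 14.1 ± 0.20 to 335 ± 61.6 (4.57 ± 0.14), and the inhibitory SMAD gene Smad6 from 0.39 ± 0.12 to 37.5 ± 4.17 (6.58 ± 0.35). Of 19 genes of the BMP and SMAD1/5 response 10 rose and 1 fell (10 and 1 adjusted over the list alone; camera 8.9e-10, 0.00031 with an estimated correlation). Visceral endoderm genes rose in 15 of 22 cases and fell in 2 (16 and 4 adjusted over the list alone; 2.2e-10 and 0.0022), such as Ttr (1.61 ± 0.11) and the regulator gene Hnf4a (1.46 ± 0.11). Epithelial genes rose in 15 of 20 cases against 1 (3.7e-12 and 0.00097), among them Cldn6 (1.80 ± 0.10) and Krt18 (1.09 ± 0.10). Mitochondrially encoded transcripts fell in 6 of 12 cases (6 adjusted over the list alone), a call of 0.027 lost at adjusted p = 0.39 with an estimated correlation, at 0.057 with the covariate and at 0.13 without replicate 1 of 24 h. Primitive endoderm genes fell in 11 of 18 cases and rose in 4 (1.3e-05 and 0.018) and parietal endoderm genes fell in 12 of 20 and rose in 2 (2.8e-06 and 0.026): Gata6 went from 306 ± 0.54 to 131 ± 12.7 CPM (−1.23 ± 0.06, adjusted p = 3e-14) and Sox7 from 129 to 49.0 CPM (−1.39 ± 0.11). The growth factor gene Fgf10 (−2.78 ± 0.17) and the guidance receptor gene Robo2 (−2.05 ± 0.17) also fell. Changed genes numbered 6371, 3117 up and 3254 down. Both 24 h libraries differed from each other more than any other pair: without replicate 2 of 24 h the count was 2240, 1158 up and 1082 down, and with only these libraries 259, 168 up and 91 down.

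After 72 h of BMP4 the cells carried products of mature visceral endoderm. The lipoprotein gene Apob went from 0 reads to 27.2 ± 2.48 CPM, at least 328-fold higher, although this call was lost with the covariate (adjusted p = 0.062). Cldn2, a claudin of leaky epithelia, reached 13.8 ± 1.67 CPM, alpha-fetoprotein Afp rose from 1.86 ± 0.09 to 54.4 ± 3.24 (4.87 ± 0.16), and Rbp4 from 43.3 to 312 CPM (2.85 ± 0.09). Unc5b (7.36 ± 0.21) and the imprinted RNA H19 (6.77 ± 0.31) rose as well, and Cgn, a tight junction gene, by 2.84 ± 0.12. Among the largest falls were Tagln (−4.45 ± 0.15), Thbs1 (−3.32 ± 0.14), and Ccn2 from 440 ± 5.39 to 62.0 ± 0.06 CPM (−2.83 ± 0.08). Of 20 parietal endoderm genes 14 fell and 2 rose (14 and 2 adjusted over the list alone; camera 3.4e-06, 0.026 with an estimated correlation), including Vim (−2.47 ± 0.08) and Thbd (−1.87 ± 0.06), while visceral endoderm genes rose in 14 of 22 cases and fell in 4 (5.9e-10 and 0.003) and epithelial genes rose in 14 of 20 against 4 (4.4e-06 and 0.017). The BMP list held 7 of 19 genes up and 4 down, a call of 0.011 lost at adjusted p = 0.053 with an estimated correlation. Mitochondrially encoded transcripts rose in 8 of 12 cases (0.0059; lost at adjusted p = 0.26), and reads outside genes stood at 10.4 per 100 gene reads against 5.66 at 0 h. Changed genes numbered 9185, 4623 up and 4562 down, but 2620 with the covariate, 1224 up and 1396 down, and 22.1% of the calls were kept. Falls were also more numerous without any 1 of the 4 libraries, as in 3975 up and 4117 down without replicate 2 of 0 h. The 0 h cells differed in serum too, so BMP4, the change of medium and time cannot be separated here.

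The FoxA2 mutants asked what this pioneer factor maintains in untreated cells. Gkn2 fell from 73.0 ± 5.02 CPM in the Gata6-FKBP line and 469 ± 4.51 in the Sox17-FKBP line to 0 reads in both mutants, at least 1075-fold and 11490-fold lower, and Gkn1 at least 301-fold and 3162-fold. In the Gata6-FKBP mutant Ttr was at least 362-fold lower and Hnf4a went from 34.0 ± 4.24 to 0.59 ± 0.33 CPM (−5.84 ± 0.18). Wls, needed for WNT secretion, appeared in both mutants, from 0 reads to 34.3 ± 0.75 CPM (at least 373-fold) and from 0.07 ± 0.04 to 30.4 ± 0.77. The receptor gene Met rose to 17.9 ± 1.82 CPM in the first, and Amn, which helps cubilin take up vitamin B12, from 0.81 ± 0.10 to 128 ± 4.32 in the second. Foxa2 RNA itself remained, at 112 ± 0.00 CPM against 124 ± 9.66 in the Gata6-FKBP line (adjusted p = 0.099) and 88.0 ± 3.85 against 120.2 ± 1.63 in the Sox17-FKBP line (adjusted p = 3.1e-06); what the mutation did to the protein is not stated. Gata6 RNA was lower in both mutants, by −1.07 ± 0.06 and −0.48 ± 0.06. Changed genes numbered 7065 in the Gata6-FKBP line, 3600 up and 3465 down, and 7397 in the Sox17-FKBP line, 3796 up and 3601 down. By at least 1 log2 unit, 1423 rose and 1187 fell in the former, and 1409 rose and 1638 fell in the latter. Falls were more numerous in the former with no filter (3393 up, 3501 down) and with only these libraries (2890 and 3085), and in the latter by DESeq2 (3519 and 3586) and without replicate 1 of its 0 h group (3120 and 3225), while without replicate 2 of its mutant both numbered 3065. Both mutants shared 1627 higher and 1662 lower genes, where 934 and 853 would be expected of independent changes, and 1106 went opposite ways.

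Gene lists were tested in each mutant against its own tagged line. In the Gata6-FKBP mutant 9 of 10 trophoblast genes rose and 1 fell (9 and 1 adjusted over the list alone; camera 1.1e-05, 0.0018 with an estimated correlation), including the placental homeobox gene Esx1 (0.86 to 37.5 CPM) and Eomes (1.08 to 14.1 CPM). Mesenchymal genes rose in 13 of 20 cases and fell in 1 (1.8e-05 and 0.012), among them Fn1 (4.28 ± 0.17) and Axl (4.64 ± 0.21). The Gata6-FKBP line was itself lower than parental cells in most of that list, Fn1 included. Movement toward the parental level was therefore not separated from an effect of the mutation. Cholesterol synthesis genes rose in 17 of 22 cases and fell in 1 (2.7e-06 and 0.009), such as Msmo1 (1.87 ± 0.10). The p53 list was higher in both mutants, with 13 of 17 up in the Gata6-FKBP line (0.0016 and 0.018; Perp 6.69 ± 0.24) and 12 of 17 up in the Sox17-FKBP line (0.0064 and 0.029; Plk2 1.33 ± 0.08). WNT response genes rose in 5 of 9 cases and fell in 1 in the former (0.0068 and 0.037), Dkk1 from 16.4 to 178 CPM. Interferon response genes fell in 11 of 14 cases and rose in 1 in the Sox17-FKBP mutant (0.00049 and 0.018), Xaf1 by −4.64 ± 0.16. Neural genes rose in 3 of 8 cases in the Gata6-FKBP mutant (0.01) and in 3 with 1 fall in the Sox17-FKBP mutant (0.033), calls lost at adjusted p = 0.054 and 0.12 with an estimated correlation, the latter also without replicate 2 of the Sox17-FKBP 0 h group (0.096) or of its mutant (0.065). Pluripotency genes rose in 8 of 12 cases and fell in 2 in the Sox17-FKBP mutant (0.018; lost at adjusted p = 0.087 with an estimated correlation). Visceral endoderm genes fell in 11 of 22 cases and rose in 6 in the Gata6-FKBP mutant (0.0046; lost at adjusted p = 0.12 with an estimated correlation).

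With FoxA2 mutant, degradation of either factor changed far fewer genes at 48 h. In the Gata6-FKBP mutant 35 genes passed, 24 up and 11 down, led by Nuak1 (16.8 ± 0.49 to 29.4 ± 0.34 CPM, 0.80 ± 0.12, adjusted p = 0.0026), Itpk1 (0.71 ± 0.10) and the BMP modulator gene Bmper (−0.82 ± 0.08, adjusted p = 5.2e-06). Vgf went from 13.8 ± 0.66 to 22.8 ± 1.42 CPM (0.72 ± 0.16, adjusted p = 0.043). Endothelial, epithelial and FGF and ERK genes were higher as lists (camera 0.00099, 1.9e-05 and 0.00027; 0.017, 0.023 and 0.028 with an estimated correlation), each with 1 member past the test: Cdh5, Krt19 and Phlda1 (1, 5 and 4 up, and 1 FGF and ERK gene down, adjusted over the list alone). In the Sox17-FKBP mutant 403 genes passed, 223 up and 180 down. The laminin gene Lama3 rose from 3.62 ± 0.28 to 17.3 ± 1.08 CPM (2.26 ± 0.24), Fst from 71.9 ± 2.32 to 189 ± 3.75 (1.40 ± 0.09), Apoe by 1.27 ± 0.11 and Hnf4a by 1.22 ± 0.11, while Sox13 fell by 1.23 ± 0.10 and Myc by 0.59 ± 0.09. Visceral endoderm genes were higher there, with 7 of 22 up and 1 down (9 and 1 adjusted over the list alone; 6.5e-11 and 0.0019), and so were primitive endoderm genes (5 of 18 up, 1 down; 4.5e-07 and 0.009). The count of 35 was 5, 1, 32 or 5 without replicate 1 or 2 of 0 h or replicate 1 or 2 of 48 h, 116 by DESeq2, 86 with no filter, 115 with the covariate, 16 with a replicate block, and 0 by edgeR with only these libraries (779 at an unadjusted p under 0.05). DESeq2's calls were 57.8% rises against 68.6% here, and with no filter falls were more numerous, at 40 up and 46 down. Without replicate 1 or 2 of 0 h Nuak1 was not called (adjusted p = 0.097 and 0.059), nor Itpk1 without replicate 2 of 0 h (0.059), nor Vgf without any 1 of these libraries (0.14 to 0.36). Cdh5 lost its call without replicate 2 of 0 h (0.17), and Krt19 and Phlda1 without either 0 h library (0.19 and 0.56; 0.21 and 0.36) or replicate 2 of 48 h (0.88 and 0.74). That of 403 was 223 (104 up, 119 down) or 157 without replicate 1 or 2 of 0 h, 183 or 194 without replicate 1 or 2 of 48 h, 699 with the covariate and 865 with only these libraries.

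**Figure D4:**
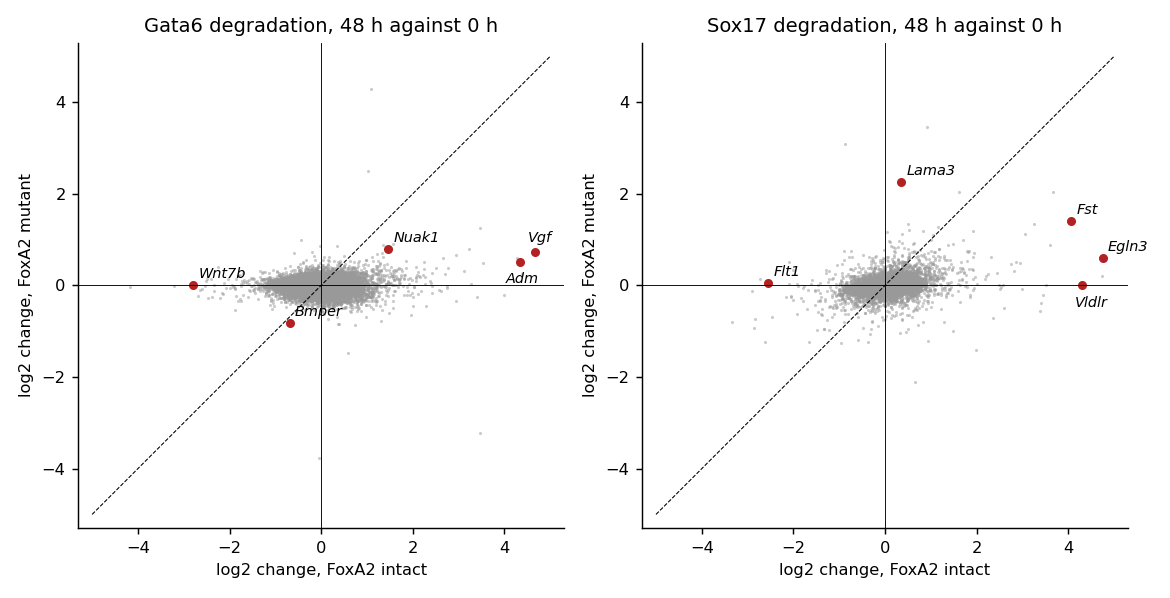
Log2 change at 48 h of degradation against 0 h with FoxA2 intact (horizontal) and mutant (vertical), for genes with a mean of at least 5 CPM over the 8 libraries, a point per gene and a dashed line of equal change. Vgf lay at 4.68 and 0.72 for Gata6 degradation, and Vldlr at 4.30 and 0.00 for Sox17 degradation.

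Direct tests of the difference bore on which responses depend on the FoxA2 background. For Gata6 degradation 3956 genes differed, 2359 more positive in the mutant and 1597 less so. Vgf (−3.96 ± 0.25), Adm (−3.82 ± 0.64) and the heparan sulfatase gene Sulf1 (−3.66 ± 0.30) rose less in the mutant. The nuclear pore gene Nup210 (3.20 ± 0.63), Wnt7b (2.81 ± 0.26), the polarity gene Crb3 (2.63 ± 0.37) and Palm3 (2.60 ± 0.18) lay on the other side. The cell cycle list differed in 18 of 24 genes (18 adjusted over the list alone; camera 9.4e-11, 0.011 with an estimated correlation) and the endothelial list in 7 of 11 (8 adjusted over the list alone; 0.00029 and 0.01). Mesoderm genes differed as a list (0.0046 and 0.024) with 2 of 9 lower and 1 higher, yet their median was 0.24 and their mean −0.89, and the call was lost without replicate 1 or 2 of the mutant's 0 h group (adjusted p = 0.98 and 0.83) or replicate 1 of its 48 h group (0.18). For Sox17 degradation 2108 genes differed, 1009 more positive in the mutant and 1099 less so (818 and 807 without replicate 2 of the mutant's 0 h group), and 4356 with only these libraries. Vldlr (−4.30 ± 0.21) and Egln3 (−4.16 ± 0.23) rose less in the mutant, where Vldlr already stood at 169 ± 0.83 CPM at 0 h against 4.79 ± 0.66 in the intact line. Egln3 also differed between mutant and intact line at 0 h. For both genes a changed response was not separated from a changed starting level. Cholesterol synthesis genes differed upward in 13 of 22 cases and downward in 1 (17 and 1 adjusted over the list alone; 9.8e-10 and 0.0013), ER stress genes downward in 13 of 18 and upward in 1 (15 and 1; 9.4e-07 and 0.036), and basement membrane genes downward in 9 of 23 (13; 7.7e-09 and 0.039).

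Set against the parental cXEN cells, the untreated tagged lines had lower levels of matrix and fibroblast genes. Col1a1, a chain of type I collagen, stood at 646 ± 126 CPM in parental cells, 0.06 ± 0.08 in the Gata6-FKBP line and 0.02 ± 0.02 in the Sox17-FKBP line. Col6a3, of type VI collagen, fell from 263 ± 29.6 CPM to 0 reads in both, at least 2859-fold and 6170-fold lower. The type IV collagen genes of basement membrane were also lower: Col4a2 fell from 7215 ± 411 to 35.5 ± 2.38 and 18.4 ± 1.08 CPM, and Col4a1 from 15010 ± 1226 to 1416 ± 101 and 3.68 ± 0.34. Of 13 fibroblast genes 11 fell and 2 rose in the Gata6-FKBP line (camera 6.9e-26, 0.00019 with an estimated correlation) and 12 fell and 1 rose in the Sox17-FKBP line (4.1e-20 and 0.00051), the same numbers adjusted over the list alone. Fibroblast feeder cells among the parental cells were not separated from lower expression within the tagged lines. Mesenchymal genes fell in 18 of 20 cases in the Gata6-FKBP line (5.4e-19 and 0.00019), Fn1 by −5.71 ± 0.18, and neural genes fell in 6 of 8 (0.0062 and 0.043). Visceral endoderm genes rose there in 16 of 22 cases against 1 (5.2e-13 and 0.00097), with Habp2 at 81.2 against 5.80 CPM and Cdh1 at 36.9 against 1.61. BMP and SMAD1/5 genes fell in 12 of 19 cases and rose in 2 in the Gata6-FKBP line (0.00068 and 0.014), and fell in 13 and rose in 2 in the Sox17-FKBP line (3.1e-06 and 0.0013). Dnmt3l rose in both lines, to 129 ± 8.43 and 21.9 ± 2.05 CPM from 0.43 ± 0.08, and Gata6 RNA was lower in both, by −1.04 ± 0.06 and −0.70 ± 0.06. Changed genes numbered 6993 and 8357.

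**Figure D5:**
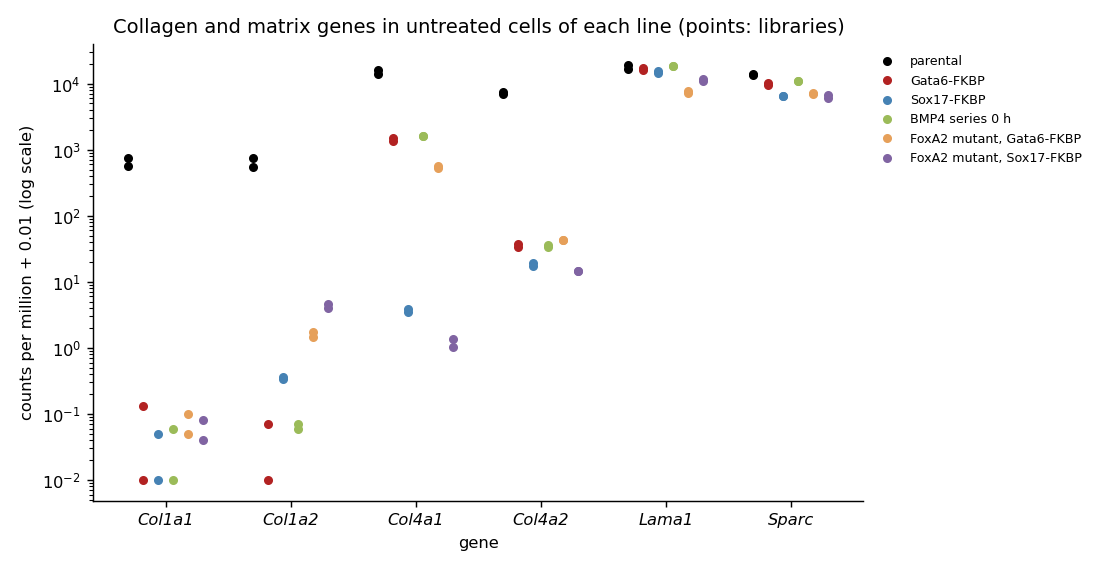
CPM plus 0.01 on a log axis for 6 collagen and matrix genes in untreated cells, a point per library, coloured by line. Parental cells lay near 646 for Col1a1 and 15010 for Col4a1, while Lama1 was 17980 in parental and 16510 in Gata6-FKBP cells.

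Over 21 comparisons and 24 lists, 183 of 504 list tests passed by camera and 82 also with an estimated correlation. For lists given above without counts adjusted over the list alone, those counts lay within 2 genes of the ones printed. The definitive endoderm and gut list passed in 0 comparisons by camera (4 at an unadjusted p under 0.05; fry, which asks only whether its genes move 1 way, called 17). The anterior visceral endoderm list passed in 1, the 48 h Sox17 degradation in the FoxA2 mutant (2 of 9 up, 0.012; lost at adjusted p = 0.054 with an estimated correlation). Without replicate 1 of that mutant's 0 h group (0.086) or replicate 2 of its 48 h group (0.097), or with no filter (0.096), the call was lost. Glycolysis and hypoxia genes passed in 14 comparisons and mitochondrially encoded genes in 4, none of which held with an estimated correlation, while ER stress genes passed in 13, 1 of which held.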

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

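Tests chosen only after the result was seen were the steps between successive times and the covariate for reads outside genes with its count of step genes. So were the direction of the 6 h genes in the FoxA2 mutants, the copies of chromosome 18 and the FoxA2 mutants against parental cells.

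The response to 48 h of Gata6 degradation differed between the intact line and the FoxA2 mutant in 3956 genes. With the covariate for reads outside genes 51.3% of these kept their direction and call. The neuropeptide precursor gene Vgf (log2 difference −3.96), the peptide hormone gene Adm (−3.82) and Sulf1 (−3.66) were more negative in the mutant, and Nup210 (3.20), Wnt7b (2.81), Crb3 (2.63) and Palm3 (2.60) more positive. For Sox17 degradation 2108 genes differed, with Adm (−4.52), Vldlr (−4.30), Egln3 (−4.16) and Sall3 (−3.95) more negative in the mutant, and the carbonic anhydrase gene Car4 (2.87), Igsf11 (2.78), the VEGF receptor gene Flt1 (2.60) and the TAM ligand gene Gas6 (2.59) more positive. Sall3 was not called without replicate 1 of the Sox17-FKBP mutant at 0 h (adjusted p = 0.28), nor Gas6 without replicate 2 of the Sox17-FKBP line at 0 h (0.13) or its replicate 1 at 48 h (0.085). At 0 h Vldlr already stood higher in the Sox17-FKBP mutant than in its intact line, and Adm and Egln3 also differed. For these genes a changed response was not separated from a changed starting level. Between Gata6 and Sox17 degradation at 48 h 2503 genes differed, with Ankrd1 (4.17), Flt1 (3.81) and Emp1 (3.45) more positive under Gata6 loss and Trmt9b (−3.93), Car2 (−3.87), Unc5b (−3.24) and Efna5 (−3.17) under Sox17 loss. Since each factor was degraded in 1 line only, the factor lost and the line were not separated there. Reads assigned to no gene, which no planned comparison uses, stood above both control libraries in 6 groups: per 100 gene reads, 7.82, 7.56 and 8.01 at 48, 72 and 96 h of Gata6 degradation (controls 5.66 and 6.11), 6.44 and 6.49 at 48 and 96 h of Sox17 degradation (5.92 and 6.01), and 10.4 at 72 h of BMP4 (5.64 and 5.69).

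Between 24 and 48 h of Gata6 degradation 7912 genes changed, with Adm and Vldlr rising and Socs3 falling, while the share of reads outside genes rose too. With that share as a covariate 3336 genes were called, 2729 of them among the 7912 and in the same direction. The change of the 7912 kept a median ratio of 0.49 (quartiles 0.18 to 0.83). The covariate's slope comes from differences within groups, which are smaller than that between 24 and 48 h. If the slope holds over the wider gap, these values argue against reads outside genes as the whole cause of the step. For the 5183 whose call ended the change shrank to a median ratio of 0.27 (quartiles 0.04 to 0.53), from a median size of 0.61 to 0.20 log2 units with standard errors of 0.14 and 0.17, and since the share moves with the groups, reads outside genes and an effect of Gata6 loss cannot be told apart for them. The FoxA2 mutant's own change from 0 to 48 h had a median ratio to the step of −0.08 (quartiles −0.22 to 0.08), so it did not repeat the step. The mutant has no 24 h sample, and the culture time of the 0 h cells is not stated. Time in culture as a cause therefore stays open. A response to Gata6 loss that sets in after 24 h may account for part of the step, as a hypothesis found and tested on the same data. Since the covariate picked the 2729 genes, no gene among them is cleared singly. The Sox17-FKBP line's own step from 24 to 48 h shared 1559 rises and 1712 falls with this step, and 328 genes went opposite ways. Independent changes would share 594 and 718. An effect common to both courses was not separated from a response to Gata6 loss.

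Degradation for 48 h changed 35 and 403 genes in the FoxA2 mutants against 5864 and 4513 in the intact lines. Over genes picked from 96 h against 24 h, 2324 and 1122, the median change in the mutant was −0.15 and 0.02 of that in the intact line. Lower precision alone would leave this median near the intact one, so the ratios argue against it as the whole cause. The standard errors (0.25 against 0.26, and 0.31 against 0.32) rest on a spread estimated per gene over all libraries. They do not measure the mutants' own spread. In the Sox17-FKBP mutant 61 of 69 called genes of 6 h kept their direction, and most did with any 1 library left out. This argues against a compound without effect only if time in culture does not move the same genes, which was not tested. A compound without effect stays open in the Gata6-FKBP mutant, where 12 of 12 kept their direction but the number called depended on single libraries. A mutant already in the late state at 0 h would carry a shift near the intact line's late change from 0 h. In the Gata6-FKBP line the median shift was −0.17 (quartiles −0.66 to 0.33), against an intact change of 0.82 from 0 to 48 h over the same genes. As a share of the change from 24 to 96 h (1.47), which starts from 24 h and not 0 h, it was −0.12. In the Sox17-FKBP line the median shift was −0.03, a share of −0.02. Its quartiles ran from −1.37 to 0.76, against 0.59 from 0 to 48 h and 1.49 from 24 to 96 h, and the question stays open. FoxA2 and other differences between the lines were not separated, nor was time in culture from the compound.

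Untreated FoxA2 mutants differed from their tagged lines in 7065 and 7397 genes, such as Gkn1 and Gkn2. For genes on chromosomes 16 and 18 in the Gata6-FKBP line a difference in copy number is a candidate explanation: their medians were −0.54 and 0.45 at 0 h and −0.51 and 0.38 in the separate 48 h libraries, where the other chromosomes lay between −0.20 and 0.11. Against parental cells chromosome 16 was 0.41 in the tagged line and −0.14 in the mutant, so a gain in the former and a loss in the latter are not told apart, chromosome 18 was 0.09 and 0.40, nearer a gain in the mutant, and indirect effects on the 6326 genes called outside chromosomes 16 and 18 were not tested. Drift of the tagged lines away from parental cells, with the mutants nearer the parental state, would place parental cells near 1 on a scale from tagged line to mutant. Their median over the 1215 genes changed by at least 1 log2 unit the same way in both lines was 0.12 and 0.23 (upper quartiles 0.62 and 0.74). For those shared genes this argues against such drift as the whole cause. Genes changed in 1 line only were not placed on the scale. Drift of the mutants themselves would also leave parental cells near the tagged line. Drift of the tagged lines in part of the genes, drift of the mutants and the FoxA2 mutation itself therefore stay open.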

How the results depend on the processing

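Chosen after the data were seen were the covariate for reads outside genes, the steps between successive times and the FoxA2 mutants against parental cells. Of 298 alternative values of 27 counts of changed genes, 255 lay within 1.5 times the reported count and 43 did not; none of the latter came from median-of-ratios scaling, whose largest shift of a median was 0.062 log2 units, though the larger of rises and falls was not stable: at Gata6 72 h it turned under it and DESeq2 (52.9 and 52.3% rises against 44.8%), and at 48 h under it (50.5 against 45.3%), with 2932 up and 2928 down at 96 h. No filter turned Sox17 6 h (36.1% rises), Sox17 24 h (47.7%), the FoxA2 mutation in the Gata6-FKBP line (49.2%), Gata6 48 h in the mutant (46.5%) and Sox17 24 to 48 h (52.2 against 45.1%). Only the libraries compared turned Sox17 6, 48, 72 and 96 h (43.7, 49.7, 49.6 and 49.3%), BMP4 24 h (64.9%) and that FoxA2 mutation (48.4%), DESeq2 turned the one in the Sox17-FKBP line (49.5%) and the covariate BMP4 72 h (46.7%) and Gata6 24 to 48 h (49.9%). With only the libraries compared, where fewer residual degrees of freedom estimate the spread, the counts were 1265 (Gata6 6 h), 1287 (Sox17 6 h), 625 (Sox17 24 h), 6895 (Sox17 48 h), 259 (BMP4 24 h), 865 (Sox17 48 h in the mutant), 4356 (Sox17 response differing in the mutant), 1126 (Sox17 24 to 48 h) and, by edgeR, 0 for Gata6 48 h in the mutant (779 at an unadjusted p under 0.05) and 0 for the Sox17 step from 6 to 24 h (1820), which is not among the 27; over all libraries edgeR called 35 and 1902 and DESeq2 116 and 2216. With the covariate they were 1087 (Gata6 6 h), 456 (Sox17 6 h), 2620 (BMP4 72 h), 115 and 699 (Gata6 and Sox17 48 h in the mutants), 3336 and 2549 (Gata6 and Sox17 24 to 48 h). DESeq2 called 383 (Sox17 6 h) and 116 (Gata6 48 h in the mutant, 57.8% rises against 68.6%), no filter 396 and 86, and the replicate block 16 for the latter. Leaving out 1 library, which removes a sample and assumes the lone one varies like the others, gave 9 (without the Gata6-FKBP 0 h replicate 1) to 2729 (without its replicate 2) for Gata6 6 h, 292 to 3463 (the same libraries) for 24 h, 73 to 87 for Sox17 6 h, 2007 to 5406 (without replicate 1 or 2 of 24 h) for Sox17 24 h, 2240 to 7272 (without replicate 2 or 1 of 24 h) for BMP4 24 h, 1 to 32 and 157 to 223 for Gata6 and Sox17 48 h in the mutants, and 2268 to 5813 (without replicate 1 or 2 of 24 h) for Sox17 24 to 48 h. For each of these counts the cause was not tested. Of 291 named gene results 259 kept their direction and side of the threshold under every setting run, 74 of the alternative values fell short of the threshold, 1 passed it newly (Sox17 at 48 h of its own degradation, with only these libraries) and 0 reversed. Of 183 list calls 79 held under every setting, 101 were lost with an estimated correlation and 26 with the covariate. With these library sizes and dispersions, drawn alike for every group, known changes of 1.5-fold were recovered in 47.6% of genes and of 4-fold in 84.1%. Depth itself was not varied, and the wider spread of some pairs was not imitated.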

Other observations

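A pair of genes, picked by eye and not from a list, differed between the lines before any treatment. Smooth muscle actin Acta2 stood at 508 ± 9.11 CPM in the Sox17-FKBP line, 9.002 ± 0.47 in the Gata6-FKBP line and 96.8 ± 9.11 in parental cells. The actin-binding gene Tagln stood at 279 ± 9.57, 22.9 ± 1.07 and 6.30 ± 1.64 in the same order. In the FoxA2 mutant of the Sox17-FKBP line they were 6.53 ± 0.79 and 10.4 ± 0.03 CPM (log2 changes −6.27 ± 0.13 and −4.74 ± 0.13). Asns, which makes asparagine and belongs to the amino acid stress response, rose in the same mutant from 135 to 852 CPM (2.65 ± 0.08). Laminin Lama1 stood at 17980 CPM in parental, 16510 in Gata6-FKBP and 14900 in Sox17-FKBP cells, where its partner in basement membrane Col4a2 was at 7215, 35.5 and 18.4. At 0 h of the BMP4 series, whose titles name XEN cells and whose genotype label the Gata6-FKBP line, Col4a1 and Col4a2 were 1619 and 35.0 CPM.

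Median log2 differences per chromosome were also read as values. Against parental cells, chromosome 6 lay at 0.33 in the Gata6-FKBP line and 0.35 in the Sox17-FKBP line, and chromosome 16 at 0.41 and 0.21. In a comparison chosen after the data were seen, the FoxA2 mutant of the Gata6-FKBP line lay at −0.14 for chromosome 16 and 0.40 for chromosome 18 against parental cells. Against their tagged lines at 0 h, the FoxA2 mutants lay at −0.54 and 0.23 for chromosome 16 and at 0.45 and 0.08 for chromosome 18.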
